A study of Mus musculus with 6 samples.

How the data were processed

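The 6 arrays are Agilent mouse whole genome oligonucleotide arrays with 59305 spots that are not controls, and hold 55681 distinct probes. Each labelling reaction used 0.5 µg of total RNA, and each array carried a pool in Cy5 and WT pool 1 RNA in Cy3, per the labels. The labels give 3 WT and 3 MUT biological replicates as pools, and the number of mice in a pool is not given in the sources used here. No dyes were swapped, so a dye effect of a probe cancels between the groups only because every array has the same orientation. The scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. All arrays were on 1 slide and in 1 scan session, per the file headers. MUT pools 1 to 3 and WT pool 1 lay in row 1 of the slide, and WT pools 2 and 3 in row 2.

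The deposited scanner files hold spot intensity as median signal and median local background in each channel, processed signals, and a log10 ratio of Cy5 to Cy3 made by the scanner software. The deposited value table holds the same log10 ratio, rounded, with a difference from the scanner files of at most 0.00499 on any array. Its median was 0 on each array, and its scale, centring and direction are therefore those of the scanner software. The log10 ratio was exactly 0 at 20.4% to 27.7% of spots. It was used as an alternative.

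The design fixed before the data were examined named mean signals. The files give median signals, which were used in their place. Background was corrected by normexp with an offset of 50 on median signal and median local background. Log2 ratios were normalized within each array by loess, with control spots at weight 0. Control spots and spots that the scanner software marked as non-uniform or population outliers were left out, and no spot was saturated. Spots of a probe were averaged. Probes were kept if well above background in Cy5 on all 3 arrays of at least 1 group, which left 29002 probes (52.1%). Computation used R 4.3.3, limma 3.58.1 and data.table (version 1.17.8), and figures used Python 3.11.15 with matplotlib 3.10.9.

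Gene names came from matching the probes' RefSeq accessions, without versions, to a table of the GRCm38.p6 assembly. This named 27509 probes of 20887 genes, and left 28172 probes without a name, of which 16194 are known by a chromosome region. The file headers name another assembly, so no coordinates are given. A gene was represented by its brightest tested probe, by mean intensity over the 6 arrays. Its value is that of this probe alone, and other probes of a gene can differ. Of 3707 genes with several tested probes, 2 had probes called in opposite directions. In 1454 of them at least 1 probe was called, and in 607 all probes were called in 1 direction.

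MUT was compared with WT by limma's lmFit and eBayes on the log2 ratios of all 6 arrays, with no covariate, Benjamini-Hochberg adjustment over all tested probes and a call at adjusted p under 0.05. Values with ± SE come from this fit with 3 arrays per group. Gene lists were tested on 1 probe per gene with camera (preset correlation 0.01, lists of at least 5 measured genes, adjustment over 38 lists), camera with an estimated correlation, and fry. Of 693 list genes 685 were on the array and 656 were tested. The lists cover 12 kidney and blood cell types and 26 pathways, and were fixed before the data were examined. The text names Bdkrb2, the 12 genes with the largest rise and the 12 with the largest fall among named genes that were called and whose pools did not overlap. It also names the list members with the smallest p, and other called list members. Some genes that this rule takes are not reported here, although counts and list tests include them.

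No fold is given for a gene whose probe was not well above background on any array of a group. Among called genes, 94 were not well above background on any WT array and 28 on any MUT array.

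The pipeline was tested on simulated data with 29002 tested probes, of which 67, 67 and 66 were changed by a log2 of 0.5, 1 and 2. It recovered 2.99%, 58.2% and 97.0% of them, and estimated median changes of 0.355, 0.793 and 1.59. Folds of this size were thus understated after background correction with an offset. Of 109 probes called, 3 (2.75%) were unchanged. The simulation changed few probes, in random directions, with the same spread in both groups. In the data 7584 of 29002 tested probes were called, so the share of false calls was not tested for changes this widespread. A list shifted by a log2 of 0.5 was found, and 0 of 20 unshifted lists had a p under 0.05. The probes were simulated independently of one another, so this does not test camera on lists of correlated genes. In the data the estimated correlation was as high as 0.81, in the intercalated cell list.

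Alternatives covered the background correction, the normalization, the filter on dim probes, the authors' value table, the Cy5 channel alone, pool number and slide row as blocks, eBayes with trend and robust, array weights, each array left out, other thresholds, other list tests and the mean of a gene's probes. A pair of settings with arrays shifted to 10 spike-in control probes was added after seeing the data. Control probes other than these and the probes without a name were not analysed further here.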

Results

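Gene expression was measured in cells sorted as collecting duct cells from newborn mouse kidneys, on 6 two-colour oligonucleotide arrays. The sort was for cells of the ureteric bud lineage, marked by a Cre driver of the Hoxb7 gene. It used GFP and tdTomato fluorescence, on salt-stressed kidneys of postnatal day 1. WT pools 1 to 3 came from mice with intact Bdkrb2, the gene of the bradykinin B2 receptor. MUT pools 1 to 3 came from mice in which Bdkrb2 was conditionally deleted in this lineage. Each pool was labelled with Cy5 and hybridised against the same RNA of WT pool 1 in Cy3, so the array of WT pool 1 compared that RNA with itself. Between 27022 and 31310 of the 55681 probes were well above background in Cy5 on each array, and the number of arrays limits the precision of every value. The log2 ratios had an SD over tested probes of 0.15 on the array of WT pool 1. This SD was 0.25 for WT pool 2 and 0.21 for WT pool 3, against 0.65, 0.55 and 0.50 for MUT pools 1, 2 and 3. MUT pools 2 and 3 were the closest pair, with an SD of 0.21 for the difference of their log ratios, and were treated as separate samples.

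The deleted gene itself could not be followed. Bdkrb2 had 1 probe, which was not well above background in either channel on any of the 6 arrays. Its log2 ratios to WT pool 1 were 0.12, 0.09 and -0.16 in WT pools 1 to 3 and -0.02, 0.05 and -0.08 in MUT pools 1 to 3. The group means were 0.02 ± 0.15 (SD, n = 3) and -0.02 ± 0.06 (SD, n = 3), an unresolved difference (exact two-sided permutation p = 0.8, where 3 against 3 pools allow no p under 0.1). Where the probe lies relative to the deleted part was not determined, so the gene gives no check of the labels.

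The comparison of MUT with WT pools asks how loss of the B2 receptor in the ureteric lineage goes with gene expression in these cells. All measured markers of principal cells (15), intercalated cells (18) and the loop of Henle and distal tubule (16) fell in MUT pools. Most of the nephron progenitor (13 of 15), stroma (11 of 16) and extracellular matrix (19 of 24) genes rose, although no list was called with an estimated correlation between genes. Gdnf, the ligand of the Ret receptor in kidney branching, was 15.8-fold higher (log2 3.98 ± 0.24 SE, n = 3 pools per group, adjusted p = 0.000365). Kcnj1, the ROMK potassium channel, was 8.76-fold lower (log2 -3.13 ± 0.25 SE, n = 3 per group, adjusted p = 0.00038). At an adjusted p under 0.05, 7584 of 29002 tested probes changed, 3351 of them higher and 4233 lower in MUT pools. By gene, 2042 rose and 2737 fell out of 14585 tested, including 492 that rose and 763 that fell at least 2-fold. The MUT and WT pools did not overlap for 7664 tested genes (52.5%, where chance gives 10%). The number of changed probes was 4890 without WT pool 1 and 3831 without WT pool 3. It was 2194 with the row of the slide as a block, which leaves WT pool 1 as the WT sample in the row of the MUT pools, and 31.5% of these were higher in MUT.

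The direction of the smaller changes is relative to the typical probe. Of the changed probes, 44.2% were higher in MUT pools after loess, and 77.3% of 6037 were with each array centred on its median, which moved the median of the tested probes by 0.23. With arrays set to the 10 spike-in control probes, a setting chosen after seeing the data, the median probe was 0.95 higher in MUT pools after loess and 0.87 higher without it. With these settings 98.9% of 19144 and 98.45% of 17055 changed probes were higher. After loess the log2 shift of the spike-ins was 0.01, 0.39 and 1.01 in WT pools 1 to 3. It was -0.70, -0.55 and -0.18 in MUT pools 1 to 3. Without loess it was 0.27, 0.03 and 0.41 against -0.59, -0.31 and 0.14, so the groups overlapped. The size of the offset, and signs that turn with it, are therefore uncertain. Values below are after loess, where the median change was near 0, and a called list whose median changes sign with the spike-in controls is named as such. That setting after loess adds 0.95 to the median of every list, so falls shrink and rises grow. Of the lists that were not called, 13 with a median under 0 turned positive there, so their medians carry no direction.

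Among the 12 genes with the largest rises were Gdnf, Fibin, Tgfbi, Bmper, Il33, Rspo1, Kazald1, Cdh11, Penk, Meis1 and Lsp1, with folds from 7.46 to 15.8. Tgfbi, an extracellular matrix protein induced by TGF-beta, rose 9.52-fold (log2 3.25 ± 0.38 SE). Bmper, a secreted regulator of BMP signalling, rose 8.86-fold (log2 3.15 ± 0.14 SE), and Rspo1, a secreted enhancer of Wnt signalling, rose 8.01-fold. Il33, a cytokine of the interleukin-1 family, rose 8.42-fold with the widest spread among MUT pools of these genes (SD 0.87). Cdh11, a mesenchymal cadherin, Penk, which encodes proenkephalin, and Meis1, a homeobox transcription factor, rose by 2.95, 2.94 and 2.94 on the log2 scale. At its other tested probe Cdh11 rose by 1.16.

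Among the 12 genes with the largest falls were Klk1b5, Klk1b26, Kng2, Kcnj1, Atp1b1, Klk1b4, Umod, Klk1b3, Kng1 and Tspan1, with folds from 7.66 to 9.96. Umod, which encodes uromodulin, a urinary protein made in the thick ascending limb, fell 7.76-fold (log2 -2.96 ± 0.31 SE). Atp1b1, the beta subunit of the sodium pump, fell 8.60-fold with log2 ratios from -4.12 to -2.64 in the MUT pools. The Klk1b kallikreins and the Kng kininogens are families of closely related genes, so which member gave a signal is uncertain.

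**Figure D1:**
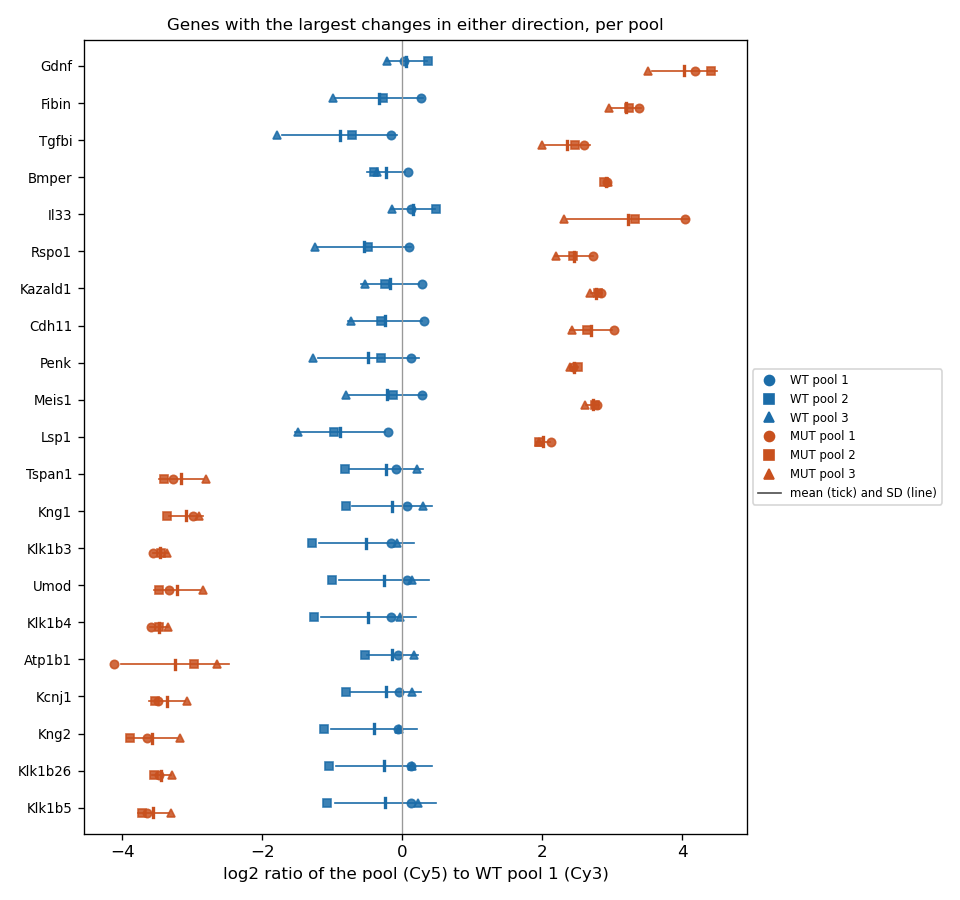
Log2 ratio of each pool to WT pool 1 RNA (x axis) for 11 of the 12 genes with the largest rises and 10 of the 12 with the largest falls (y axis), with WT pools in blue, MUT pools in orange, a tick for the mean and a line for the SD of 3 pools. The MUT pools lie between 1.95 and 4.41 for the genes that rose and between -4.12 and -2.64 for those that fell.

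Of 38 gene lists fixed before the data were examined, 23 were shifted by camera with a preset inter-gene correlation of 0.01, 9 higher and 14 lower in MUT pools. None of the 23 was called with an estimated correlation, and the directional fry test called 25. The endothelium list had an estimated correlation of -0.02, under the preset one, and still a camera adjusted p of 0.254. The same 0.254, the lowest of any list in the test with an estimated correlation, was reached at correlations up to 0.45 (principal cells). A high correlation is thus not the only reason for the lost calls, and a value of 0.254 does not separate lists by their correlation. Counts of genes adjusted over the list alone are the same as those over all probes tested unless given.

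All 15 measured marker genes of principal cells, which reabsorb sodium and water in the collecting duct, fell in MUT pools (list median log2 -1.90, and -0.96 with the spike-in controls after loess, adjusted p = 0.254 with an estimated correlation). Aqp2 and Aqp3, water channels of these cells, fell by 1.67 ± 0.11 (SE) and 1.90 ± 0.09 (SE) on the log2 scale. Avpr2, the vasopressin V2 receptor, fell by 2.09 ± 0.14 (SE), Scnn1a, a subunit of the epithelial sodium channel, by 2.27 ± 0.18 (SE), and Fxyd4, a regulator of the sodium pump, by 2.57 ± 0.17 (SE). All 18 measured markers of intercalated cells, the acid and base secreting cells of the same duct, also fell (median -2.25, and -1.30 with the spike-in controls after loess, adjusted p = 0.309 with an estimated correlation). Slc26a4, which encodes the anion exchanger pendrin, fell by 2.70 ± 0.25 (SE), and Foxi1, the transcription factor of these cells, fell by 2.42 ± 0.21 (SE). Slc4a9, Dmrt2, Hmx2 and Oxgr1 fell by 2.50, 2.43, 2.61 and 2.38. The intercalated cell median was -0.46 in WT pool 2 against 0.09 in WT pool 1. Beside these falls, the median of the renal stroma list was 1.65 higher in MUT pools.

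Of 17 measured genes of the ureteric trunk and collecting duct lineage, 15 fell and none rose (median -1.63, and -0.68 with the spike-in controls after loess, adjusted p = 0.268 with an estimated correlation). Here 15 fell and 1 rose adjusted over the list alone. Mal fell by 2.49 ± 0.17 (SE), Krt7, an epithelial keratin, by 2.06 ± 0.16 (SE), Tfcp2l1 by 2.11 ± 0.19 (SE) and Gata3, a transcription factor of the ureteric epithelium, by 1.63 ± 0.40 (SE). Hoxb7, whose Cre driver marked the cells, fell by 0.69 ± 0.12 (SE), but was 0.26 higher with arrays set to the spike-in controls after loess. The 2 members that did not pass, named after their values were seen, were Lhx1 at 0.83 ± 0.28 (SE) and Pax2 at 0.29 ± 0.16 (SE). The ureteric bud tip list was not shifted (median -0.07, camera adjusted p = 0.994). Of its 16 measured genes 1 fell, Wnt9b, by 0.97 ± 0.20 (SE). The receptor Ret, named after its value was seen, was at -0.12 ± 0.38 (SE). WT pool 2 stood apart in this list with a median log2 ratio of 0.79, against 0.02 and 0.23 in WT pools 1 and 3.

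Nephron progenitor and early nephron genes moved the other way: 13 of 15 measured rose and none fell (median 1.57, adjusted p = 0.254 with an estimated correlation). All 15 rose adjusted over the list alone. Six2 and Cited1, transcriptional regulators of the nephron progenitors, rose by 2.56 ± 0.25 (SE) and 2.13 ± 0.33 (SE). The other tested probe of Six2 was at 1.27. Wnt4, which acts when progenitors become epithelial, rose by 2.13 ± 0.20 (SE), and Wt1 by 2.62 ± 0.43 (SE). Uncx rose by 1.71. Tmem100 rose by 2.43 and was well above background on 1 of 3 WT arrays. In the renal stroma list 11 of 16 measured genes rose and 1 fell (median 1.65, adjusted p = 0.393 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell. Pdgfra, a stromal growth factor receptor, rose by 2.29 ± 0.24 (SE), Tcf21 by 2.46 ± 0.30 (SE), Foxd1, a transcription factor of the stromal progenitors, by 1.62 ± 0.34 (SE) and Col1a1 by 2.06 ± 0.39 (SE). Ren1, the renin gene, was the member that fell, by 0.61 ± 0.10 (SE), and was 0.34 higher with arrays set to the spike-in controls after loess. The stromal medians were -0.90 and -0.97 in WT pools 2 and 3 against 0.08 in WT pool 1. With the slide row as a block, which sets WT pools 2 and 3 apart, the stroma difference was 1.04 with a lower quartile of -0.03.

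Loop of Henle and distal tubule genes, which belong mostly to segments outside the collecting duct and share 1 gene with the ureteric trunk list, fell in all 16 measured cases (median -2.02, and -1.08 with the spike-in controls after loess, adjusted p = 0.309 with an estimated correlation). Slc12a1, the sodium, potassium and chloride cotransporter of the thick ascending limb, fell by 2.71 ± 0.23 (SE), and Slc12a3, the thiazide-sensitive cotransporter of the distal tubule, by 2.60 ± 0.31 (SE). Kcnj10, Cldn10 and Irx1 fell by 2.74, 2.21 and 1.60. The proximal tubule list was not called (camera adjusted p = 0.0786, with 0.000174 to 0.395 over the alternatives), although 3 of 17 measured genes fell, Kap by 1.47, Slc5a2 by 1.15 and Miox by 1.24. The list was called lower than the other genes without WT pool 2 (adjusted p = 0.000174), without MUT pool 1 (0.046), with the slide row (0.000316) or pool number (0.025) as a block, and with array weights (0.0197). It was also called with median centring (0.0289), with no filter on dim probes (0.0382) and with the spike-in controls (0.014 after loess and 0.0382 without it). WT pool 2 had a proximal tubule median of -0.94 and a loop of Henle median of -0.68, against 0.04 and 0.05 in WT pool 1. The podocyte list was not called either (camera adjusted p = 0.0768, with 7.5e-05 to 0.834 over the alternatives), with 3 of 11 measured genes higher. It was called without WT pool 1 (adjusted p = 7.5e-05), with pool number as a block (0.0374), with median centring (0.0168), with no filter on dim probes (0.0478) and with the spike-in controls (0.000186 after loess and 0.00012 without it). Its median turned from 0.21 to -0.37 with the slide row as a block, and was -0.97 and -0.86 in WT pools 2 and 3 against 0.10 in WT pool 1. Among those that rose, Wt1 also stands in the progenitor list and Tcf21 in the stroma list.

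Endothelial genes fell in 12 of 15 measured cases and rose in none (median -0.85, but 0.10 with arrays set to the spike-in controls after loess, adjusted p = 0.254 with an estimated correlation). There were 14 that fell adjusted over the list alone. Sox17, Egfl7 and Robo4 fell by 1.08, 1.02 and 1.04, and Ehd3, an endocytic protein of glomerular endothelium, by 2.02 ± 0.28 (SE). Leukocyte genes rose in 12 of 15 measured cases and fell in 1 (median 0.94, adjusted p = 0.403 with an estimated correlation). Cx3cr1, a chemokine receptor of macrophages, rose by 1.36 ± 0.26 (SE), Cd52 by 1.26 ± 0.22 (SE), C1qb, a complement component, by 1.23 ± 0.24 (SE) and Coro1a by 0.84 ± 0.16 (SE). Other tested probes of Cx3cr1 were at 1.27, which was called, and 0.73, which was not. Ptprc, the leukocyte antigen CD45, fell by 0.43 ± 0.11 (SE) but was 0.52 higher with arrays set to the spike-in controls after loess. The leukocyte medians were -0.42 and -0.68 in WT pools 2 and 3 against -0.01 in WT pool 1, and 0.66, 0.80 and 0.26 in MUT pools 1 to 3. Their difference was 0.62 with the slide row as a block. Erythroid genes fell in 7 of 8 measured cases (median -1.92, and -0.97 with the spike-in controls after loess, adjusted p = 0.382 with an estimated correlation). Hba-a2, an alpha globin with a near-identical copy, fell by 2.57 ± 0.42 (SE), and Alas2, of heme synthesis, by 1.97 ± 0.29 (SE). Slc4a1, also an intercalated cell gene, fell by 2.60. Bpgm fell by 0.58 but was 0.37 higher with arrays set to the spike-in controls after loess. The erythroid median was -1.15 in WT pool 2 against -0.08 in WT pool 1.

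**Figure D2:**
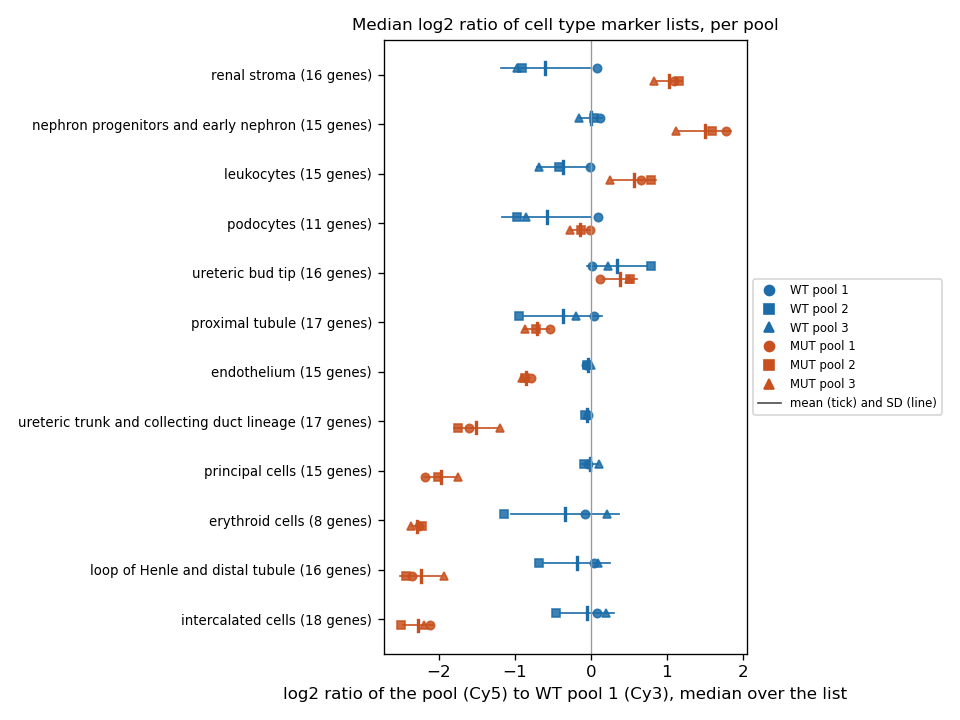
Median log2 ratio to WT pool 1 RNA over each cell type marker list (x axis) for each pool, with lists on the y axis, WT pools in blue, MUT pools in orange, a tick for the mean and a line for the SD of 3 pools. Principal cells lie near 0 in WT pools and between -2.18 and -1.74 in MUT pools, while nephron progenitor genes lie between 1.12 and 1.78 in MUT pools.

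The kallikrein-kinin and renin-angiotensin list, which holds the deleted receptor's own pathway, changed in both directions and was not called (5 of 15 measured genes rose, 7 fell, median -0.30, camera adjusted p = 0.359, with 0.0211 to 0.574 over the alternatives). With arrays set to the spike-in controls after loess it was called lower relative to the other genes (adjusted p = 0.0211), with a median of 0.65 where that of all probes was 0.95. Without loess the adjusted p was 0.0296. Over the pools, without the spike-in controls, the list median was -0.055, -0.497 and -0.107 in WT pools 1 to 3. It was -0.352, -0.655 and -0.673 in MUT pools 1 to 3, so WT pool 2 lay within their range. Klk1, tissue kallikrein, fell by 2.77 ± 0.29 (SE), and the kininogens Kng1 and Kng2, precursors of bradykinin, fell by 2.94 ± 0.27 (SE) and 3.17 ± 0.31 (SE). Klkb1, plasma kallikrein, fell by 1.20 ± 0.12 (SE), and Mme, neprilysin, which degrades kinins, by 1.01 ± 0.14 (SE). Atp6ap2, the prorenin receptor, fell by 0.89 but was 0.06 higher with arrays set to the spike-in controls after loess. Agtr2, the angiotensin type 2 receptor, rose by 1.57 ± 0.20 (SE), Cpm, a carboxypeptidase, by 1.49 ± 0.18 (SE) and Cpn1 by 0.75 ± 0.21 (SE). Agtr1b also rose (adjusted p = 0.000506), but was not well above background on any WT array, so no fold is given. In the same pools the principal cell and loop of Henle lists had medians of -1.90 and -2.02.

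Sodium and potassium transport genes fell in 19 of 22 measured cases and rose in 2 (median -1.39, and -0.44 with the spike-in controls after loess, adjusted p = 0.268 with an estimated correlation), and 6 of the list's genes are also principal cell markers. Sgk1, an aldosterone-induced kinase, fell by 1.71 ± 0.12 (SE) and Tmprss2, a serine protease, by 2.21 ± 0.16 (SE). Slc12a2, a basolateral cotransporter, rose by 0.84 ± 0.15 (SE) and Kcnma1, the BK potassium channel, by 0.48 ± 0.12 (SE). In the vasopressin and water transport list 8 of 16 measured genes fell and 3 rose (median -0.42, but 0.53 with arrays set to the spike-in controls after loess, adjusted p = 0.328 with an estimated correlation). Of the list's genes 4 are also principal cell markers. Avpr1a, the vasopressin V1a receptor, fell by 1.98 ± 0.22 (SE) and Aqp4, 1 of these 4, by 2.04 ± 0.12 (SE). Akap12 and Prkar2b, an anchor and a regulatory subunit of protein kinase A, rose by 1.30 ± 0.21 (SE) and 0.99 ± 0.15 (SE). Another tested probe of Akap12 was at 0.10 and was not called. Adcy3 was the third to rise, with no fold given since it was not well above background on any WT array. Hypertonic stress response genes fell in 9 of 14 measured cases and rose in none (median -0.70, but 0.25 with arrays set to the spike-in controls after loess, adjusted p = 0.254 with an estimated correlation). Adjusted over the list alone, 10 fell. Slc14a2, a urea transporter, fell by 2.30 ± 0.23 (SE), Slc5a3, which takes up the osmolyte inositol, by 2.05 ± 0.39 (SE) and Akr1b3, which makes sorbitol, by 0.64 ± 0.09 (SE). At its other tested probe Slc14a2 was at -0.33 and was not called. Akr1b3 was 0.31 higher with arrays set to the spike-in controls after loess. The principal cell and loop of Henle lists fell in the same pools.

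Epithelial junction and polarity genes fell in 17 of 25 measured cases and rose in 1 (median -0.93, but 0.02 with arrays set to the spike-in controls after loess, adjusted p = 0.254 with an estimated correlation). Cdh1, the gene of E-cadherin, fell by 1.52 ± 0.13 (SE), the claudins Cldn4 and Cldn8 by 1.83 ± 0.13 (SE) and 2.00 ± 0.21 (SE), and Tjp3 by 1.34 ± 0.13 (SE). Tjp1, a tight junction scaffold, rose by 0.36 ± 0.11 (SE). Extracellular matrix and mesenchymal genes rose in 19 of 24 measured cases and fell in 1 (median 1.19, adjusted p = 0.275 with an estimated correlation). As many as 21 rose adjusted over the list alone. Cdh2, the gene of N-cadherin, rose by 2.38 ± 0.21 (SE), Snai2, a transcription factor of mesenchymal cells, by 2.49 ± 0.24 (SE) and Fbn1, the gene of fibrillin-1, by 1.41 ± 0.12 (SE). S100a4 fell by 1.38 ± 0.13 (SE). The list median was -0.36 and -0.40 in WT pools 2 and 3 against -0.01 in WT pool 1, and the difference was 0.96 with the slide row as a block. The list shares 4 genes with the stroma list, which rose in the same pools, while the principal cell and loop of Henle lists fell.

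DNA replication genes rose in 22 of 25 measured cases and fell in none (median 0.57, adjusted p = 0.254 with an estimated correlation), and 23 rose adjusted over the list alone. Mcm3, Mcm4 and Mcm6, subunits of the replicative helicase, rose by 1.10, 0.82 and 0.89, and Gins1 by 0.73. Genes of G2 and mitosis rose in 17 of 22 measured cases and fell in none (median 0.58, adjusted p = 0.254 with an estimated correlation), and 20 rose adjusted over the list alone. Cenpe, a kinetochore motor, rose by 0.99 ± 0.11 (SE), Top2a, a topoisomerase, by 0.85 ± 0.12 (SE), Ccna2 by 0.79 ± 0.11 (SE) and Mki67 by 0.64 ± 0.10 (SE). The nephron progenitor list rose in the same pools.

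Wnt and beta-catenin targets rose in 9 of 17 measured cases and fell in 1 (median 0.72, adjusted p = 0.268 with an estimated correlation). Adjusted over the list alone, 10 rose and 2 fell. Dkk1, a secreted Wnt antagonist, rose by 2.43 ± 0.13 (SE), Nkd1 by 1.20 ± 0.17 (SE), Tnfrsf19 by 1.19 ± 0.16 (SE) and Sp5 by 1.17 ± 0.15 (SE), while Rnf43, a ligase that removes Wnt receptors, fell by 0.96 ± 0.14 (SE). The other tested probe of Tnfrsf19 was at 0.09 and was not called. Notch pathway genes rose in 8 of 17 measured cases and fell in 2 (median 0.26, camera adjusted p = 0.0453, adjusted p = 0.435 with an estimated correlation). The adjusted p ran from 0.00549 to 0.104 over the alternatives, and the call was lost without MUT pool 2 (0.0513), without MUT pool 3 (0.104), with Agilent's processed signals (0.0832) and in the authors' value table (0.0834). It was also lost with no background subtraction (0.0535), with the Cy5 channel alone (0.0855) and with the mean of a gene's probes (0.0722). Hey1 and Heyl, transcriptional targets of Notch, rose by 1.83 ± 0.18 (SE) and 1.65 ± 0.18 (SE), Lfng by 1.16 ± 0.17 (SE) and Notch2 by 1.00 ± 0.13 (SE). Notch2 was at 0.11 and not called at its other tested probe. The ligands Jag2 and Dll4 fell by 0.66 ± 0.18 (SE) and 0.56 ± 0.15 (SE), but with arrays set to the spike-in controls after loess they were 0.29 and 0.39 higher. The nephron progenitor list, which shares 2 genes with the Notch list, and the stroma list rose in the same pools.

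Oxidative phosphorylation genes fell in 23 of 24 measured cases (median -0.92, but 0.03 with arrays set to the spike-in controls after loess, adjusted p = 0.381 with an estimated correlation), and 24 fell adjusted over the list alone. Cycs, cytochrome c, fell by 1.42 ± 0.16 (SE), Cox6c by 1.29 ± 0.16 (SE) and Cyc1 by 1.28 ± 0.16 (SE). Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 1.90 ± 0.33 (SE). Atp5a1, a subunit of ATP synthase, fell by 0.93 ± 0.12 (SE) and was 0.02 higher with arrays set to the spike-in controls after loess. The list median was -0.42 in WT pool 2 against 0.04 in WT pool 1. Hypoxia and glycolysis genes fell in 15 of 23 measured cases and rose in 1 (median -0.60, but 0.35 with arrays set to the spike-in controls after loess, adjusted p = 0.393 with an estimated correlation). Aldoa, Pfkp and Gpi1, enzymes of glycolysis, fell by 1.64, 1.45 and 1.04, and Slc2a1, a glucose transporter, by 1.17. Pfkp was at -0.24 and not called at its other tested probe. Hk2, hexokinase 2, rose by 1.20 ± 0.27 (SE). The collecting duct and loop of Henle lists fell in the same pools.

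Immediate early and tissue dissociation genes fell in 12 of 21 measured cases and rose in 2 (median -0.42, but 0.52 with arrays set to the spike-in controls after loess, adjusted p = 0.254 with an estimated correlation). Ier3 fell by 2.01 ± 0.16 (SE), Atf3 by 1.46 ± 0.12 (SE), Klf4 by 1.37 ± 0.10 (SE) and Klf6 by 1.00 ± 0.10 (SE), while Hspa1a, a heat shock protein, rose by 1.13 ± 0.15 (SE) and Myc by 0.78 ± 0.15 (SE). NRF2 oxidative stress genes fell in 7 of 18 measured cases and rose in none (median -0.28, but 0.66 with arrays set to the spike-in controls after loess, camera adjusted p = 0.0329, adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone, 8 fell. The adjusted p ran from 0.0101 to 0.081 over the alternatives, and the call was lost with the Cy5 channel alone (0.0661), without MUT pool 3 (0.0681) and with the spike-in controls and no loess (0.081). Gclc, of glutathione synthesis, fell by 1.48 ± 0.23 (SE), Sod2, the mitochondrial superoxide dismutase, by 1.24 ± 0.13 (SE) and Srxn1 by 1.20 ± 0.14 (SE). Gsta4 fell by 0.66 but was 0.29 higher with arrays set to the spike-in controls after loess. Ribosomal protein genes were called higher as a list (median 0.19, camera adjusted p = 0.00716) although none of the 28 passed on its own, and the list had an adjusted p = 0.575 with an estimated correlation. Rpl5 and Rpl7 were at 0.34 ± 0.13 (SE) and 0.27 ± 0.10 (SE). The adjusted p ran from 0.000164 to 0.169 over the alternatives, and the call was lost with Agilent's processed signals and in the authors' value table (0.169 in each) and with the spike-in controls after loess (0.124). In the same pools the principal cell and loop of Henle lists fell, and the nephron progenitor and stroma lists rose.

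Other lists were not called and held genes that moved in both directions. Of 28 measured p53 targets 6 rose and 8 fell (camera adjusted p = 0.353), or 7 and 11 adjusted over the list alone. Phlda3 rose by 1.61 ± 0.11 (SE) and Perp fell by 1.09 ± 0.14 (SE). Cdkn1a, the cell cycle inhibitor p21, fell by 0.83 ± 0.10 (SE) but was 0.12 higher with arrays set to the spike-in controls after loess. Of 18 prostaglandin and nitric oxide genes 3 rose and 6 fell (camera adjusted p = 0.388), or 3 and 8 adjusted over the list alone. Ptgis, prostacyclin synthase, rose by 2.43 ± 0.26 (SE), Gucy1a1, a subunit of guanylate cyclase, rose by 2.07 ± 0.17 (SE), and Nos3, endothelial nitric oxide synthase, fell by 1.11 ± 0.12 (SE). Of 17 genes of Ret, FGF and receptor tyrosine kinase signalling 2 rose and 5 fell (camera adjusted p = 0.8), or 3 and 5 adjusted over the list alone, with Fgfr1 up by 1.32 and Hbegf down at -1.46. Of 20 genes of TGF-beta and BMP signalling 5 rose and 3 fell (camera adjusted p = 0.736), with Tgfb3 up by 1.87. Its median was -0.08 while its mean was 0.20, and camera gave the direction of the mean. Of 18 cilium and cystic disease genes 2 rose and 4 fell (camera adjusted p = 0.694), or 4 and 5 adjusted over the list alone. Cys1 fell by 1.04, and Bicc1 fell by 0.81 but was 0.14 higher with arrays set to the spike-in controls after loess.

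The lists of general cell stress and survival were not called. Of 20 interferon response genes 2 rose and 4 fell (camera adjusted p = 0.212, but 0.046 without MUT pool 1 and 0.046 to 0.498 over the alternatives), with Oasl2 up by 0.89 and Cxcl10 at -1.26. Of 17 genes of NF-kappaB and inflammation 1 rose and 2 fell (camera adjusted p = 0.994). Vcam1 rose by 1.54, but was at 0.29 and not called at its other tested probe. The list median was -0.04 while its mean was 0.07, where camera gave the higher and fry the lower direction. Cxcl1 was at -0.92, but was 0.03 higher with arrays set to the spike-in controls after loess. Of 20 genes of endoplasmic reticulum stress 1 rose and 2 fell (camera adjusted p = 0.212), with Edem1 up by 0.61. Ppp1r15a was at -0.69, but was 0.26 higher with arrays set to the spike-in controls after loess. Of 17 heat shock proteins 1 rose, Hspa1a, and 2 fell (camera adjusted p = 1), with Cryab at -1.32. Its median was 0.00 and its mean -0.10, where camera gave the higher and fry the lower direction. Of 20 cholesterol synthesis genes 1 rose and 4 fell (camera adjusted p = 0.226), or 1 and 3 adjusted over the list alone. Msmo1 was at -0.62, but was 0.33 higher with arrays set to the spike-in controls after loess. Of 21 apoptosis regulators 2 rose and 4 fell (camera adjusted p = 0.504), with Apaf1 up by 0.87. Pmaip1 was at -0.85, but was 0.10 higher with arrays set to the spike-in controls after loess.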

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

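The settings that use the spike-in controls were chosen after seeing the data; the other settings were not. The 7584 changed probes became 2194 with the slide row as a block, 4490 at a change of at least 1.5-fold, 19144 with loess and the spike-in controls, and 17055 with the spike-in controls and no loess. Leaving out 1 array gave 3831 to 9536, with 4890 without WT pool 1 and 3831 without WT pool 3. The fold limit can only lower the count. For the other settings the cause was not tested. With the slide row as a block, which compares the MUT pools with WT pool 1, all 7584 probes kept their direction. The pools did not overlap for 4767 of the 4779 called genes, so for these the direction was fixed beforehand. With the spike-in controls, 4553 (loess) and 4793 (no loess) kept their direction. A block of pool number gave 7245 probes, although the pools of like number correlated at only 0.143, 0.0723 and 0.197. The 23 shifted lists ranged from 21 to 25, except for 0 with an estimated correlation. The Bdkrb2 difference was 0.16 in the authors' value table, 0.91 with loess and the spike-in controls and 0.51 with no loess, against -0.03, and -0.12 to 0.02 with 1 array left out. Of 159 called genes named in the Results above, 141 kept their direction under all 21 settings run for genes, and 83 also kept their call. The genes of the families below were not counted. Dim signal limits Bdkrb2, which was not well above background on any array.

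Some lists that were not called turned in the direction of their test, which compares them with the other genes, and the cause was not tested. The ureteric bud tip median was -0.055 with Agilent's processed signals, -0.062 with no background subtraction, 0.016 with Cy5 alone, -0.055 in the authors' value table, 0.29 with the slide row as a block, 0.058 with array weights, -0.069 with the mean of a gene's probes, 0.22 with median centring, 0.88 and 0.86 with the spike-in controls (loess and no loess) and -0.29 to 0.17 with 1 array left out. The heat shock median was 0.033 with processed signals, 0.00060 with no filter, 0.033 in the value table, 0.040 with the slide row, -0.011 with array weights, 0.95 with loess and the spike-in controls and -0.025 to 0.053 with 1 array left out. The NF-kappaB median was -0.034 with no background subtraction, -0.052 with array weights and -0.067 to 0.027 with 1 array left out. The Ret and FGF median was 0.011 with the slide row, 0.075 with array weights and -0.13 to 0.0042 with 1 array left out. The podocyte median was -0.37 with the slide row, and the cilium median was -0.24 to 0.046 with 1 array left out. The medians themselves turned positive in 11 lists without a call with median centring, to between 0.0050 and 0.26, and in 13 with the spike-in controls, to between 0.58 and 0.91 with loess and between 0.42 and 0.90 without. Ret was 0.18 with median centring, 0.56 with the slide row, 0.075 with array weights and -0.46 to 0.38 with 1 array left out.

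With loess and the spike-in controls, values turned to 0.26 for Hoxb7, 0.83 for Ret, 0.34 for Ren1, 0.52 for Ptprc, 0.37 for Bpgm, 0.057 for Atp6ap2, 0.12 for Cdkn1a, 0.31 for Akr1b3, 0.29 for Jag2, 0.39 for Dll4, 0.14 for Bicc1, 0.021 for Atp5a1, 0.027 for Cxcl1, 0.26 for Ppp1r15a, 0.29 for Gsta4, 0.33 for Msmo1 and 0.10 for Pmaip1. With the spike-in controls and no loess they turned to 0.28 for Hoxb7, 0.82 for Ret, 0.25 for Ren1, 0.0078 for Egfl7, 0.42 for Ptprc, 0.34 for Bpgm, 0.033 for Atp6ap2, 0.064 for Cdkn1a, 0.34 for Akr1b3, 0.14 for Jag2, 0.17 for Dll4, 0.24 for Bicc1, 0.045 for Gpi1, 0.17 for Atp5a1, 0.31 for Ppp1r15a, 0.25 for Gsta4, 0.32 for Msmo1 and 0.030 for Pmaip1. These settings move the median of all tested probes by 0.95 and 0.87.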

Other observations

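The gene families here, the tests of cell composition and of scale, and the splits of the probe count were chosen only after the result was seen. All 5 measured uroplakins, membrane proteins of the urothelium, fell in MUT pools, with Upk3a down 6.95-fold (log2 -2.80 ± 0.25 SE, n = 3 per group) and Upk1a 4.72-fold. Their median of -1.71 was -0.76 with loess and the spike-in controls, where 2 of the 5 were called, and -1.09 with the spike-in controls and no loess, where 3 were. It was -2.92 with Agilent's processed signals and in the authors' value table, and 4 fell with the slide row as a block. The metallothioneins Mt1 and Mt2, which bind zinc and copper, fell by 2.27 ± 0.28 (SE) and 2.12 ± 0.23 (SE), and both were also called lower with the spike-in controls, where their median went from -2.20 to -1.25 (loess) and -1.14 (no loess). Of 15 measured subunits of the V-ATPase proton pump outside the intercalated cell list, 11 fell (median -1.01), but 5 did with median centring and 0 were called with the spike-in controls.

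Hox genes, which pattern the body axis, were counted by cluster, with no test between clusters. In the HoxC cluster 5 of 6 measured genes rose, with Hoxc10 up by 1.27 ± 0.09 (SE) and Hoxc9 by 1.44 ± 0.18 (SE), and all 6 were higher with the spike-in controls. In the HoxA cluster 4 of 10 rose and none fell, with 1 called without WT pool 3 or with the slide row as a block, and 8 higher with the spike-in controls. In the HoxD cluster 4 of 8 fell and 1 rose, but with the spike-in controls 3 were higher and none lower. In the HoxB cluster 4 of 8 fell, but none did with median centring or with the slide row as a block, and the median turned from -0.45 to 0.50 with loess and the spike-in controls. Of 11 fibrillar collagens 9 rose, including Col3a1 by 2.45 ± 0.40 (SE) and Col2a1 by 2.18 ± 0.15 (SE), but 5 did without WT pool 2, 5 without WT pool 3, 6 without MUT pool 2 and 3 with the slide row as a block. Of 6 type IV collagens, which form basement membranes, 3 fell, but 1 did without WT pool 1, WT pool 3, MUT pool 2 or MUT pool 3, with median centring or with the slide row as a block, and 3 were higher with the spike-in controls.

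Collecting duct and loop of Henle genes fell while nephron progenitor and stromal genes rose. A lower share of ureteric-derived cells of every kind alike would lower tip and principal cell genes by about as much. The ureteric bud tip median lay 1.84 above that of the principal cells, beyond their quartile ranges, which argues against it. This holds only if the tip genes came from ureteric cells alone, which was not tested. A loss that spared the tips would give the same values, so it stays open. A higher share of every other cell type alike would raise stroma and loop of Henle genes alike. The stroma median lay 3.68 above the loop of Henle median, so the lists did not rise alike. That difference is part of the pattern itself and is not a separate test. A shift of scale as the whole cause is argued against by the loop of Henle median. It shrank from -2.02 but was still -1.08 with loess and the spike-in controls, with an upper quartile of -0.52. More cells of the nephrogenic zone and fewer mature tubule cells among the sorted cells may account for the pattern. A sort for cells of the Hoxb7 lineage is meant to leave out progenitor, stroma and loop of Henle cells. Yet 16 of 16 measured loop of Henle, 16 of 16 stroma and 14 of 15 progenitor markers were well above background on all 3 WT arrays. RNA of these genes was thus present in the WT pools too. Whether it came from such cells passing the gate was not tested. The difference between these groups of lists was 2.72 higher in the lowest MUT pool than in the highest WT pool, but that value restates the pattern and decides nothing. The sort and the genotype cannot be told apart in this design, and an effect of the genotype itself stays open and untested.

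The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05, and every split but the real one keeps part of the difference between the genotypes. The real split was 1 of 10 with as many changed probes, 7584 against a highest other of 0 by limma, with up to 1218 probes at an unadjusted p under 0.05 in the others and 11340 in the real split. For shifted lists it was 1 of 10, with 23 against a highest other of 21.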
